A study of Homo sapiens with 2 samples.

How the data were processed

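The series measured total RNA of SAS cells, an established line from a human tongue squamous cell carcinoma, on 2 two-colour Agilent arrays. Cells were transfected with small interfering RNA (siRNA) for 48 h. On each array, per the labels, RNA of cells given control siRNA (siControl) was labelled with Cy3 and RNA of cells given siRNA against DDX3 (siDDX3) with Cy5. Each labelling started from 0.2 µg of total RNA and each hybridisation used 0.3 µg of labelled cRNA, per the labels' protocols. The 2 arrays were labelled as biological replicates 1 and 2. Both carried the dyes the same way round, so a dye effect and the siRNA effect of a probe share 1 sign on both arrays. The arrays lay on 1 slide and were scanned together, so neither slide nor scan could be fitted.

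The deposited scanner files hold, per the file headers, the mean intensity of each spot in each channel and the median intensity of its local background, both unnormalized, from Agilent Feature Extraction 10.5.1.1. They also hold processed intensities that the scanner software had background-subtracted and dye-normalized, and the log10 of the red over the green processed signal, per the file headers. A p-value of each spot's log ratio, from the software's error model within 1 array, was deposited too. The values deposited for the series as a whole are that same p-value to 2 decimals (96.6% and 96.4% lay within plain rounding, with a largest difference of 0.0055 and medians 0.41 and 0.49 for replicates 1 and 2). They are no expression values and have no direction or centring, and they were not used as an alternative measure of expression.

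Mean intensities were background-corrected with normexp (offset 50) and normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 (R 4.3.3, statmod 1.5.0, version 1.17.8 of data.table). Spots marked as outliers by the scanner software were left out (271 and 269), and spots of a probe were averaged. A probe was tested if it was well above background in at least 1 channel on both arrays. A gene was represented by its brightest tested probe. The log2 ratio of siDDX3 over siControl was tested against 0 with lmFit and eBayes with an intensity trend, with Benjamini-Hochberg adjustment over 31290 genes and a threshold of 0.05. SDs are between the 2 arrays, and p-values of single genes measure the spread between these samples. With 2 arrays the test leans on the spread of all genes (17.1 prior degrees of freedom), and the number of arrays limits its precision.

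Of 58201 probes, 31104 (53.4%) were named through their accession in the RefSeq genes of GRCh38.p14, 3366 through a symbol and 496 through a synonym. The other 23235 kept the name in the file. Coordinates are those of the files, on hg19.

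Gene lists were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over 27 lists), with an estimated correlation and with fry as alternatives. With the preset correlation camera takes its degrees of freedom from the number of genes, not of arrays. Its p-values compare a list with the other genes and do not measure the spread between the arrays. The lists covered interferon-stimulated genes, NF-kB cytokines, growth factors, AP-1 and immediate early genes, ATF4 targets, the unfolded protein response, heat shock proteins, mesenchymal genes, matrix proteases, integrins and laminins, epithelial junctions, basal keratinocyte genes, keratinocyte differentiation, Wnt, TGF-beta, YAP, hypoxia and glycolysis, cholesterol synthesis, DNA replication, mitosis, p53 targets, NRF2 targets, ribosomal proteins, translation initiation factors, DEAD-box helicases and oxidative phosphorylation, and 1 further list that was tested with the others but is not reported here. A further 3 lists held markers of fibroblasts, leukocytes and endothelial cells. Named genes were DDX3X, the 12 largest rises and 12 largest falls among called genes of at least median intensity with the same sign on both arrays and no placeholder symbol, and up to 4 called members of each list with the largest absolute log2 ratio. Genes named outside this rule (the mitochondrial probes and members of gene families) were chosen after their values were seen. The test, the lists, the rule for named genes and most of the other settings tried were fixed before the data were examined.

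The other settings changed the background correction, the normalization, the filter on dim probes, the outlier spots, the handling of several probes of a gene and the test, and left out each replicate. Another 3 were added after seeing the data: a correction for the base composition of the probe, a restriction to genes in the RefSeq table, and centring on genes of like intensity. Figures were drawn with matplotlib 3.10.9.

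The fit was tested on simulated data with the real intensities of these 31290 genes and a spread drawn around their trend with intensity. It recovered 98 of 100 genes changed by 0.5 and 100 of 100 changed by 1 on the log2 scale, and it called 12 of 31090 unchanged genes (5.71% of calls). With no change simulated it called 0 genes. With 1 of 27 lists shifted, camera called 1 list. The simulation held no dye effect. Its noise followed the model that the fit assumes. It changed 100 genes at each size, where 11238 genes were called in the data, so its rates do not carry over to the real arrays. The simulation also drew each gene independently, so it cannot show how often camera calls an unshifted list whose genes vary together.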

Results

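DDX3 (gene symbol DDX3X) is a DEAD-box RNA helicase that acts in translation, and the comparison asks which transcripts of SAS cells differ in level 48 h after siRNA against it. The data are 2 two-colour arrays of 62976 spots each, 1 for each of 2 biological replicates, with siControl in Cy3 and siDDX3 in Cy5. On replicate 1, 74.4% of the gene spots were well above background in Cy3 and 70.2% in Cy5. On replicate 2 these shares were 70.2% and 66.9%. No gene spot was saturated. Across genes, which are not independent replicates, the log2 ratios of the 2 arrays had a Pearson correlation of 0.869, and their median absolute difference was 0.09. Among 300 probes with 10 spots per array, 36.7% differed between the arrays by over 3 standard errors of the spot noise, which does not tell separate cultures from repeat labellings of 1 RNA. The arrays were counted as 2 samples because the labels call them biological replicates.

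DDX3X itself fell most among the named genes, with a log2 ratio of -2.78 ± 0.22 (SD, n = 2; adjusted p = 2.03e-15), or 6.87-fold lower in siDDX3. It stood at -2.94 on replicate 1 and -2.62 on replicate 2. The value rests on 1 tested probe, at chromosome X from 41208627 to 41208686 (hg19, plus strand). PTX3, a secreted pattern recognition protein, fell by 2.17 on the log2 scale (SD 0.016, n = 2), and AREG, a ligand of the EGF receptor, fell by 2.02 (SD 0.062). CCN2, a matricellular protein, fell by 1.98 (SD 0.081), and COL8A1, a collagen chain, fell by 1.92 (SD 0.076). With the scanner software's processed signals CCN2 stood at -2.85 and COL8A1 at -2.61, below PTX3 (-2.30) and AREG (-1.95). TXNIP and ARRDC4, both alpha-arrestins that restrain glucose uptake, rose by 2.01 (SD 0.23) and 1.75 (SD 0.27). On hg19 the probe of PTX3 lies on chromosome 3 from 157160969 to 157161028, that of AREG on chromosome 4 from 75320518 to 75320577 and that of TXNIP on chromosome 1 from 145442447 to 145442506.

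The other large falls were those of RIMS2, a presynaptic scaffold (-1.94 ± 0.11, SD, n = 2), the long noncoding RNA MANCR (-1.79 ± 0.14), the adhesion protein TENM2 (-1.69 ± 0.12) and the transcriptional co-regulator IFRD1 (-1.67 ± 0.0014). FAM72A followed at -1.58 ± 0.13, with near-identical paralogs that its probe may not separate. The kinase anchoring protein AKAP12 fell to -1.55 ± 0.07 and DUSP6, a phosphatase of ERK, to -1.53 ± 0.35. AREG, MANCR, TENM2 and AKAP12 had further tested probes, and all of these lay below 0, those of MANCR at -0.58 and -1.31.

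Among the large rises, CYRIB stood at 1.82 ± 0.12 (SD, n = 2), and ARL6IP1, a protein that shapes the endoplasmic reticulum, at 1.81 ± 0.031. The glycosyltransferase GALNT7 rose by 1.77 (SD 0.16), the metallothionein MT1F by 1.69 (SD 0.19) and the sorting protein PACS2 by 1.60 (SD 0.17). CYTH3, an exchange factor for ARF proteins, rose by 1.56 (SD 0.23). IMPACT, an inhibitor of the kinase GCN2, and the transcription factor LMO2 each rose by 1.53 (SD 0.25 and 0.18). MTRNR2L6 and MTRNR2L1 rose by 1.95 (SD 0.18) and 1.91 (SD 0.22). These are nuclear near-copies of the mitochondrial 16S ribosomal RNA, and their probes may not separate the copies from it.

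**Figure D1:**
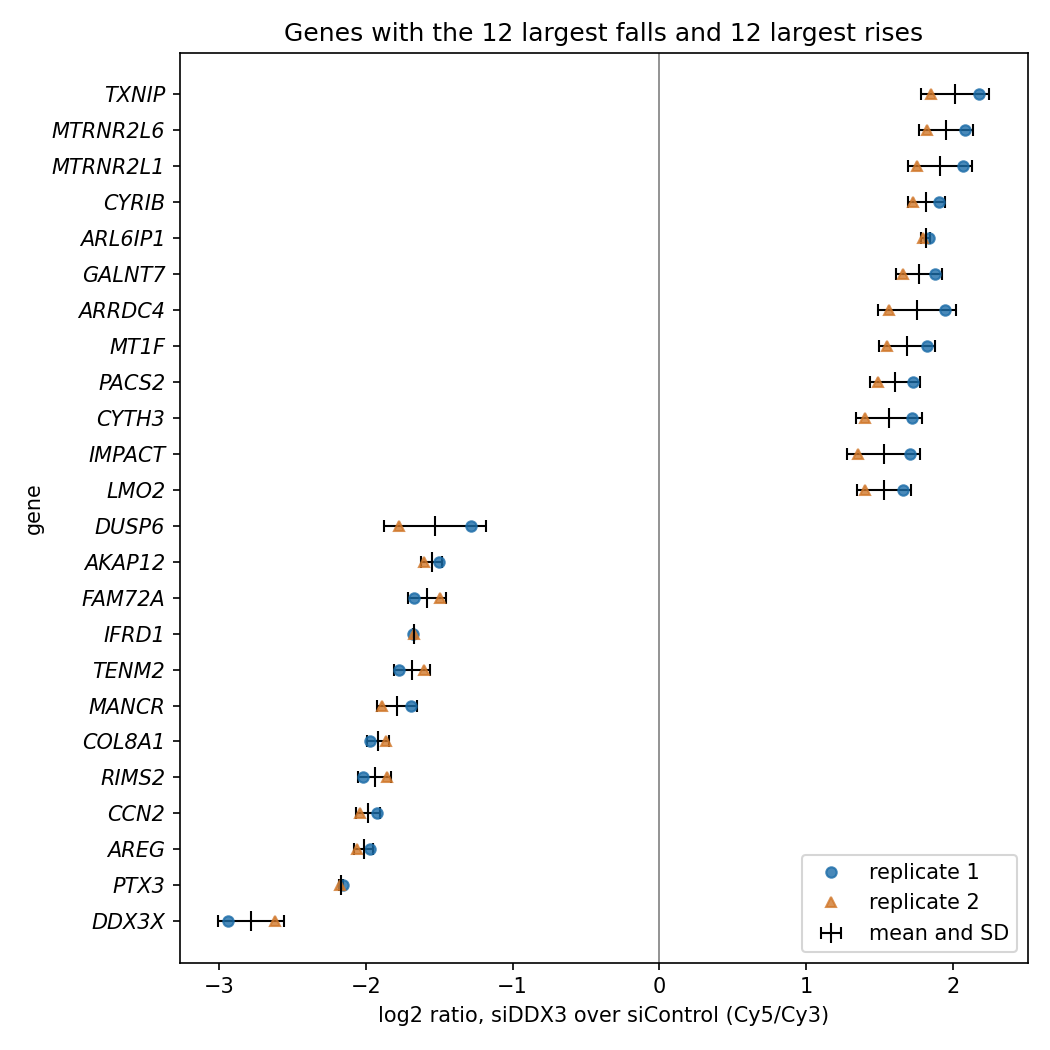
Log2 ratio of siDDX3 over siControl (x axis) for the 12 genes with the largest falls and the 12 with the largest rises (y axis), with each replicate as a point and the mean ± SD of the 2 arrays in black. DDX3X lies lowest at -2.78 and TXNIP highest at 2.01, and every point of a gene lies on the same side of 0.

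Over all 31290 genes tested, 5412 were higher and 5826 lower in siDDX3 at an adjusted p under 0.05 (limma). Of these 11238 genes, 11225 had the same sign on both arrays. With an absolute log2 ratio of at least 1, 132 were higher and 175 lower. These counts were 297 and 604 with processed signals, 557 and 81 with median centring and 1710 and 27 with no normalization. With the mean over the probes of a gene they were 93 and 143, and 233 of the 307 genes stayed past 1. The spread between the arrays (their distance from their mean) reached 1 for 3 genes. Most calls were small: 8643 (76.9%) had an absolute log2 ratio under 0.5. With no dye swap, a dye effect of a probe is not separated from the siRNA effect, and the split depended on the scaling: 48.2% of calls were higher as fitted, 79.1% with median centring in place of loess (12089 higher, 3195 lower) and 97.4% with no normalization (26844 higher, 724 lower). The median of all genes stood at 0.0068 as fitted, 0.11 with median centring and 0.40 with no normalization. Median centring used the median of all gene spots, before the filter on dim probes, so the tested genes stayed above 0. No setting was scaled to the spike-in controls, which read higher in Cy5 than designed by 1.15 and 1.07 (log2, replicates 1 and 2). That would shift ratios down rather than up, so these settings do not bound the share of higher calls from below. The offset also holds any error in adding the spike-ins.

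Genes of cell division were lower. Of 49 mitosis genes, 46 fell and 0 rose (median log2 ratio -0.47; camera adjusted p = 4.53e-19; adjusted p = 0.655 with an estimated correlation). CENPA, the centromeric histone, stood at -1.44 ± 0.20 (SD, n = 2), the kinetochore gene NDC80 at -1.22 ± 0.13, the proliferation marker MKI67 at -0.88 ± 0.042 and CKS1B, a partner of cyclin-dependent kinases, at -0.84 ± 0.085. Among 48 genes of DNA replication and E2F targets, 40 fell and 2 rose (median -0.41; camera adjusted p = 5.80e-15; adjusted p = 0.655 with an estimated correlation). The ribonucleotide reductase subunits RRM1 and RRM2 fell by 1.21 (SD 0.14) and 1.08 (SD 0.21), E2F2 by 1.17 (SD 0.32) and the primase subunit PRIM1 by 1.04 (SD 0.097). A dimmer RRM2 probe stood at 0.084. Adjusted over the list alone, 46 mitosis genes and 42 replication genes fell. With no normalization both lists' medians lay above 0 (0.11 and 0.17) but below that of all genes, by 0.28 and 0.23.

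Targets of ATF4, the transcription factor of the amino acid response, were lower too: 25 of 38 fell and 4 rose (median -0.32; camera adjusted p = 3.39e-07; adjusted p = 0.655 with an estimated correlation). Asparagine synthetase (ASNS) stood at -1.37 ± 0.079 (SD, n = 2), the glutamine transporter SLC1A5 at -1.19 ± 0.052, the glutathione-degrading enzyme CHAC1 at -1.16 ± 0.14 and DDIT3 at -1.06 ± 0.11. A dimmer CHAC1 probe stood at -0.32. Of 28 AP-1 and immediate early genes, 15 fell and 2 rose (median -0.28; camera adjusted p = 8.82e-05; adjusted p = 0.655 with an estimated correlation). Besides DUSP6, KLF2 fell by 0.98 (SD 0.15), EGR1 by 0.76 (SD 0.14) and IER3 by 0.68 (SD 0.06). Adjusted over the list alone, 27 ATF4 targets and 17 AP-1 genes fell. With no normalization these medians stood at 0.20 and 0.27, below that of all genes by 0.20 and 0.12.

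Of 32 genes of cholesterol synthesis and SREBP2 targets, 21 fell and 4 rose (median -0.29; camera adjusted p = 8.82e-05; adjusted p = 0.655 with an estimated correlation). HSD17B7 fell by 1.06 (SD 0.12), squalene epoxidase (SQLE) by 0.81 (SD 0.062), MSMO1 by 0.78 (SD 0.015) and FDFT1 by 0.73 (SD 0.037). Other HSD17B7 probes of like brightness stood at -0.94 and -0.24. Among 24 basal keratinocyte genes, 14 fell and 3 rose (median -0.17; camera adjusted p = 0.0262; adjusted p = 0.759 with an estimated correlation). PTHLH fell by 1.14 (SD 0.17), SOX2 by 0.86 (SD 0.21), keratin KRT6A by 0.70 (SD 0.15) and the desmosomal cadherin DSG3 by 0.59 (SD 0.057). Adjusted over the list alone, 21 cholesterol genes and 14 basal keratinocyte genes fell. With median centring neither list passed (camera adjusted p = 0.154 and 0.518), and both medians stayed below that of all genes, by differences of -0.083 and -0.042.

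Translation factors and helicases were called in both directions. Of 49 translation initiation factors, 26 fell and 11 rose (median -0.13; camera adjusted p = 0.0457; adjusted p = 0.655 with an estimated correlation), but the list was higher with median centring in place of loess (median 0.26; camera adjusted p = 0.0216). EIF4H, a cofactor of the helicase EIF4A, fell by 1.02 (SD 0.11), the cap-binding inhibitor EIF4EBP2 by 1.00 (SD 0.11) and EIF4A1 by 0.69 (SD 0.23). The poly(A)-binding protein PABPC1 rose by 0.66 (SD 0.022). A dimmer EIF4EBP2 probe stood at 0.53. Among 45 other DEAD-box and DEAH-box helicases, 22 fell and 7 rose (median -0.09; camera adjusted p = 0.0108; adjusted p = 0.655 with an estimated correlation), and with median centring the median was 0.15 (camera adjusted p = 0.708). DDX59 fell by 0.78 (SD 0.022), DHX9 by 0.62 (SD 0.13), DDX21 by 0.52 (SD 0.033) and DDX55 by 0.51 (SD 0.045), but with median centring DDX21 was not called (-0.079). Adjusted over the list alone, 26 initiation factors and 22 helicases fell.

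Subunits of oxidative phosphorylation were higher: 47 of 58 rose and 2 fell (median 0.33; camera adjusted p = 9.95e-14; adjusted p = 0.655 with an estimated correlation). COX6C rose by 0.74 (SD 0.025), NDUFB9 by 0.71 (SD 0.0014), COX7B by 0.70 (SD 0.02) and UQCRC2 by 0.67 (SD 0.039). Genes of like intensity outside the list had a median of -0.024. Probes placed on the mitochondrial chromosome, chosen after their values were seen, were higher on both arrays for 9 of 10, with a median of 0.44. In the authors' deposited scanner statistics, the spike-in controls also read higher in Cy5 than designed, by 1.15 and 1.07 on the log2 scale on replicates 1 and 2.

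Among 76 cytosolic ribosomal protein genes, 67 rose and 2 fell (median 0.37; camera adjusted p = 1.02e-18; adjusted p = 0.655 with an estimated correlation). RPS18 stood at 1.01 ± 0.036 (SD, n = 2), RPS2 at 0.97 ± 0.014, RPL12 at 0.91 ± 0.012 and RPS21 at 0.82 ± 0.036. These are among the brightest genes of the arrays, and genes of like intensity outside the list had a median of 0.34. Relative to those, the median of the ribosomal protein genes was 0.041, and centring on genes of like intensity ended the call (median 0.034; camera adjusted p = 0.146), in a setting added after seeing the data whose neighbours include the ribosomal protein genes themselves. These values come from the brightest probe of each gene, which for RPS18, RPS2 and RPS21 was also the highest: other bright probes stood at 0.43 and 0.22 for RPS18, 0.53 and 0.094 for RPS2 and 0.29 for RPS21, and a dim RPS21 probe at -0.23. With the scanner software's processed signals the median of the list was 0.10 (camera adjusted p = 0.0157). Adjusted over the list alone, 69 ribosomal protein genes and 48 oxidative phosphorylation genes rose.

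Of 37 interferon-stimulated genes, 19 rose and 6 fell (median 0.25; camera adjusted p = 0.00264; adjusted p = 0.655 with an estimated correlation). The signal transducer IRF9 rose by 1.32 (SD 0.12), the membrane protein IFITM1 by 0.88 (SD 0.034), IFIT3 by 0.71 (SD 0.065) and PARP9 by 0.63 (SD 0.022). A second IRF9 probe, a dimmer one, stood at -0.075, and a second PARP9 probe at 0.15. Adjusted over the list alone, the counts were 19 and 6 as well. With no normalization the list did not pass (camera adjusted p = 0.0857).

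**Figure D2:**
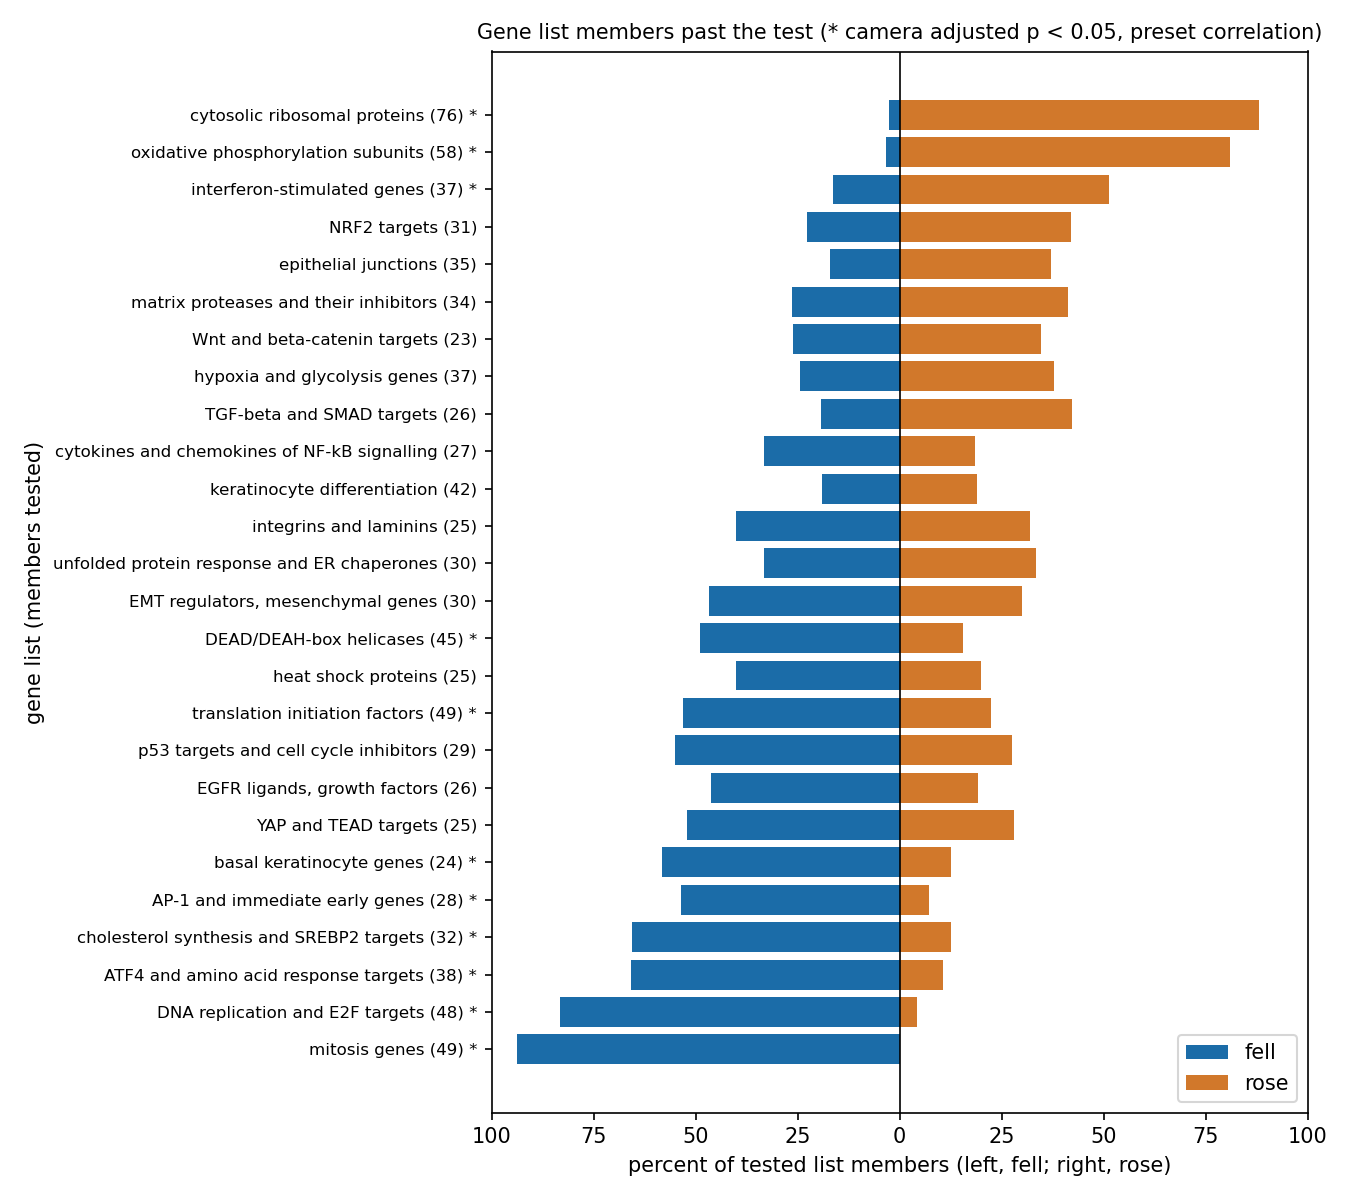
Percent of the tested members of each gene list that fell (left) or rose (right) in siDDX3 past an adjusted p of 0.05, with lists ordered by median log2 ratio, members tested in brackets and an asterisk where camera with a preset correlation passed. Mitosis genes lie at the bottom, with 46 of 49 fallen, and ribosomal protein genes at the top, with 67 of 76 risen, where genes of like intensity had a median of 0.34.

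The other lists reported here did not pass camera as fitted, though single members were called. Calls were common in general: of 15973 protein-coding genes tested, 4029 were higher and 4206 lower. Counts of list members near those shares thus show nothing particular to a list. Those shares were not matched on intensity, so counts above them in a bright list need not be particular to it either. The standard error was smaller for brighter genes, such as 0.039 for RPS18 at a mean log2 intensity of 17.2 against 0.080 for KLF2 at 7.55. With median centring in place of loess, 4 of these other lists passed as higher: epithelial junctions, integrins and laminins, hypoxia and glycolysis genes, and NRF2 targets. Among 27 NF-kB cytokines, 9 fell, with PTGS2 at -1.81 ± 0.20 (SD, n = 2), CXCL1 at -1.49 ± 0.086 and IL1B at -0.81 ± 0.11, while 5 rose, with RELB at 0.92 ± 0.011. Their median was 0.03 and their mean -0.13 (camera adjusted p = 0.529). Of 26 growth factors 12 fell, and besides AREG the EGF receptor ligand EREG fell by 1.41 (SD 0.05) and VEGFC by 0.74 (SD 0.15). FGF2 was among the 5 that rose, at 0.81 ± 0.14 (camera adjusted p = 0.133). YAP targets fell for 13 of 25 and rose for 7 (camera adjusted p = 0.059). Besides CCN2, LHFPL6 was 2.15-fold lower, while ARHGEF17 rose by 0.83 (SD 0.30) and MYOF by 0.78 (SD 0.061). Dimmer MYOF probes stood at 0.22 and 0.19. Of 29 p53 targets and cell cycle inhibitors 16 fell and 8 rose (camera adjusted p = 0.256), with CDKN2C at -1.20 ± 0.34, RRM2B at -0.69 ± 0.20, CDKN2D at -0.58 ± 0.12 and CDKN1C at 0.51 ± 0.045. A dimmer RRM2B probe stood at -0.24. TGF-beta targets rose for 11 of 26 and fell for 5 (camera adjusted p = 0.486), with PMEPA1 at 1.26 ± 0.42, SMAD6 at 0.98 ± 0.054 and LTBP3 at 0.59 ± 0.011. A second PMEPA1 probe of like brightness stood at 0.25. With median centring the medians of growth factors and p53 targets stayed below that of all genes (differences of -0.081 and -0.0060), while that of YAP targets, below 0 as fitted, lay above it by 0.074. In counts adjusted over the list alone, 7 NF-kB cytokines rose and 9 fell, 7 growth factors rose and 12 fell, 7 YAP targets rose and 14 fell, 8 p53 targets rose and 16 fell, and 11 TGF-beta targets rose and 7 fell.

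Of 30 mesenchymal genes 14 fell and 9 rose (camera adjusted p = 0.486). The intermediate filament VIM fell by 1.39 (SD 0.22) and the protease FAP by 0.96 (SD 0.092), whereas COL6A1 rose by 0.90 (SD 0.07) and SPARC by 0.88 (SD 0.085). With median centring this list had a median of 0.13. Epithelial junction genes rose for 13 of 35 and fell for 6 (camera adjusted p = 0.053), with OVOL1 at 0.91 ± 0.0051, CLDN4 at 0.80 ± 0.14, GRHL3 at 0.79 ± 0.22 and CLDN1 at -0.74 ± 0.06. A dimmer GRHL3 probe stood at -0.21 and a dimmer CLDN4 probe at 0.12. Of 25 integrin and laminin genes 10 fell and 8 rose (camera adjusted p = 0.987), with DST at -1.36 ± 0.058, ITGB8 at -0.94 ± 0.23, LAMC1 at 0.66 ± 0.13 and ITGA2 at 0.50 ± 0.22. The highest of 6 DST probes stood at 0.098. Their median was -0.017 and their mean -0.031, although camera ranked the list upward. With median centring the medians of junction genes (0.36) and of integrins and laminins (0.33) passed (camera adjusted p = 0.00129 and 0.031). Keratinocyte differentiation genes were called for 8 rises and 8 falls among 42 (camera adjusted p = 0.956), with ZNF750 at 0.69 ± 0.39, LORICRIN at 0.59 ± 0.13 and EMP1 at -0.71 ± 0.076. Their median was 0.0074, although camera ranked the list downward. When adjusted over the list alone, 10 mesenchymal genes rose and 15 fell, 15 junction genes rose and 6 fell, 9 integrin and laminin genes rose and 10 fell, and 8 differentiation genes rose and 9 fell.

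Matrix proteases and their inhibitors rose for 14 of 34 and fell for 9 (camera adjusted p = 0.278), with ADAM8 at 1.29 ± 0.29 (SD, n = 2), TIMP4 at -1.22 ± 0.032, CTSB at 0.71 ± 0.13 and MMP15 at 0.66 ± 0.10. The lowest of 3 ADAM8 probes stood at -0.098. Of 31 NRF2 targets 13 rose and 7 fell (camera adjusted p = 0.166). Heme oxygenase HMOX1 rose by 1.47 (SD 0.20), ferritin heavy chain FTH1 by 1.25 (SD 0.047) and ABCC3 by 0.87 (SD 0.16), while AKR1C3 fell by 0.80 (SD 0.072). Hypoxia and glycolysis genes rose for 14 of 37 and fell for 9 (camera adjusted p = 0.133), with the hexokinase HK2 at 1.12 ± 0.16, EGLN1 at 0.80 ± 0.073, GPI at 0.58 ± 0.082 and the lactate transporter SLC16A3 at -0.71 ± 0.11. Wnt targets rose for 8 of 23 and fell for 6 (camera adjusted p = 0.486), with NKD2 at 1.34 ± 0.14, LGR4 at 0.46 ± 0.033, DKK1 at 0.44 ± 0.078 and BMP4 at -0.51 ± 0.049. With median centring the medians of NRF2 targets (0.34) and hypoxia genes (0.42) passed (camera adjusted p = 0.0216 and 0.000768). With p-values adjusted over the list alone, 17 protease genes rose and 10 fell, 14 NRF2 targets rose and 7 fell, 16 hypoxia genes rose and 11 fell, and 9 Wnt targets rose and 6 fell.

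Genes of the unfolded protein response were called for 10 rises and 10 falls among 30 (camera adjusted p = 0.769), with HSPA13 at -0.88 ± 0.0026, PDIA4 at -0.72 ± 0.13, MANF at -0.48 ± 0.06 and ERN1 at 0.58 ± 0.21. A dimmer ERN1 probe stood at 0.095. Of 25 heat shock proteins 10 fell and 5 rose (camera adjusted p = 0.131), with HSPH1 at -0.55 ± 0.092, CHORDC1 at -0.54 ± 0.098, HSPA4L at -0.44 ± 0.16 and HSPA8 at -0.41 ± 0.15. With median centring HSPH1, HSPA8 and MANF were not called (-0.10, 0.10 and -0.013). Tested and adjusted over the list alone, 10 genes of the unfolded protein response rose and 11 fell, and 5 heat shock proteins rose and 11 fell.

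Markers of other cell types were mostly not called. Of 7 tested fibroblast markers, PDGFRB (-1.29 ± 0.23, SD, n = 2) and FAP fell and 5 did not pass. Of 13 leukocyte markers, LCP1 (-0.40 ± 0.0062) and CORO1A (-0.18 ± 0.024) fell and 11 did not pass. Of 6 endothelial markers, EMCN rose (0.24 ± 0.14) and 5 did not pass.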

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

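The tests of the mitochondrial probes and of the ribosomal protein genes were chosen after their values were seen. A first version for the mitochondrial probes had pooled all matched probes, which let 1 dim probe with many neighbours set the level (share 0.128), and it was replaced by matching each probe on its own.

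The spike-in controls lie outside the comparison of genes and showed a signal in the deposited scanner statistics. Their log10 ratio was offset from the designed one by 0.348 on replicate 1 and 0.322 on replicate 2, or 2.23-fold and 2.10-fold toward Cy5, in which siDDX3 was labelled. The ratios of the 10 spike-ins followed the design with a correlation of 0.976 and 0.980 and a slope of 0.892 and 0.893.

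The mitochondrial probes form the first pattern: 9 of 10 were higher on both arrays, with COX2 at 0.74, ND4L at 0.92 and ATP6 at 0.32, and a median of 0.44. Without loess, nuclear probes of like intensity reached 0.489 of the mitochondrial median, and 10.55% of them lay at or above their mitochondrial probe, so an intensity-dependent dye trend could account for part of the unnormalized rise. With loess a rise remained among nuclear probes as bright as COX2, ND4L and CYTB (medians 0.33, 0.31 and 0.25), while 9 of the 10 mitochondrial probes lay above their matched nuclear median, by a median of 0.43 over the 10. A lower yield of cytosolic messenger RNA in siDDX3 would raise mitochondrial probes and spike-ins alike, yet the mitochondrial median lay below the spike-in offset, at a difference of -0.67 with loess, though without loess it lay 0.84 above the array median and so nearer that offset. A difference of that size was set as excluding this cause, but that bound was wrong. The mixes were added to each labelling separately, and the offset also holds any error in adding them. The mitochondrial median also left out the MTRNR2L probes, which may not separate nuclear near-copies from mitochondrial ribosomal RNA. With loess all 10 MTRNR2L probes were higher on both arrays. Their median was 1.29, against spike-in offsets of 1.15 and 1.07 (log2, replicates 1 and 2). A COX1 probe, also left out, stood at 1.34. The shortfall against the spike-ins thus holds only for the 10 probes in the mitochondrial median. Lower yield of cytosolic messenger RNA and an effect of siDDX3 itself both stay open.

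The rise of ribosomal protein genes is the second pattern. Without loess, genes of like intensity outside the list reached 0.951 of their median (95% bootstrap interval 0.876 to 1.06). Loess left a trend at the bright end, where 195 other genes above a mean log2 intensity of 16 had a median of 0.30. A dye trend among the brightest probes is thus a candidate explanation for most of this rise, and these arrays hold no dye swap to separate it from an effect of siDDX3 on abundant transcripts.

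Calls with an absolute log2 ratio under 0.5 are the third pattern. Of 2436 such genes with a second tested probe that did not overlap the first, 71.0% shared the sign (exact binomial 95% interval 69.1% to 72.8%), against 85.1% for larger calls and 56.3% for genes not called. That argues against a dye bias independent between the probes of a gene as the whole cause, since it would give an even split. The interval takes genes as independent trials, so it does not measure the spread between the arrays. Genes not called also lay above an even split, and the small calls exceeded their share too. Base counts of the probe explained 3.30% of the variance of these ratios, which argues against base composition as the main cause. A bias shared by the probes of a transcript could remain, such as one of intensity where their brightness is alike. Of the 11238 calls of any size, 10712 were also made when centred on genes of like intensity, 27 of them with the opposite sign. With loess, genes grouped by mean log2 intensity up to 16 already had medians between -0.049 and 0.023. That centring could thus change few calls there, and it does not decide the question.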

How the results depend on the processing

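The cause of the changes below was not tested except where stated, and 3 alternatives (base composition, RefSeq genes, genes of like intensity) were chosen after seeing the data. DDX3X stayed past the threshold in every fit, from -3.01 with the scanner software's processed signals to -2.25 with no normalization, and ranged from -2.94 to -2.62 on single arrays. With 1 array, which allows no test, 109 to 171 genes reached a log2 ratio of 1 and 160 to 227 reached -1. Processed signals gave 297 genes higher and 604 lower at an absolute log2 ratio of at least 1, and an offset of 10 gave 305 lower. Median centring gave 12089 higher and 3195 lower, with 557 and 81 at that size, and no normalization gave 26844 and 724, with 1710 and 27. A test against a fold of 1.5 gave 349 and 380, which follows from its stricter null. Of 11238 called genes, 8706 were also called with median centring, 530 of them with the opposite sign. Of 307 genes past a log2 ratio of 1, 307 kept call and sign with median centring, 305 unnormalized and 307 centred on like intensity. Of these, 212, 159 and 293 stayed past 1.

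Median centring called 9 lists higher and 4 lower, against 3 and 8 as fitted. Growth factors passed as lower with no normalization (adjusted p = 0.00561), YAP targets as lower (0.0283) and junctions as higher (0.0224) with no filter on dim probes, and heat shock proteins as lower with probe means (0.0384). An estimated correlation called 0 and 0, and fry called 1 (oxidative phosphorylation) and 1 (YAP targets; both adjusted p = 0.0301). With 2 arrays both tests have 1 residual degree of freedom per gene, so these losses say little about stability. Among 126 named genes over the alternatives with a test, 59 values lost the call (48 in the test against a fold) and 14 turned. With median centring (all genes 0.11) HSPA8 stood at 0.10 and CORO1A at 0.043, and HSPH1, MANF and DDX21 lost their calls (-0.10, -0.013 and -0.079). With processed signals 8 named genes moved by over 1.5-fold relative to all genes, to -2.85 for CCN2, -2.61 for COL8A1, -2.65 for PTGS2, 2.31 for LMO2, -1.58 for FAP, -1.96 for PDGFRB, 1.64 for SMAD6 and -1.17 for BMP4, and with median centring 2 did (RPS2 at 1.67, RPS21 at 1.51). With no normalization IER3 (0.039), DDX21 (0.21), DDX55 (0.069), HSPH1 (0.19), CHORDC1 (0.050), HSPA4L (0.084), HSPA8 (0.40), SLC16A3 (0.056), LCP1 (0.044), CORO1A (0.34), EIF4A1 (0.062) and MANF (0.28) lay above 0, where all genes had a median of 0.40.

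Lists for which camera changed direction had these medians. Integrins and laminins, ranked upward by camera as fitted at a median of -0.017, were ranked downward at -0.10 with processed signals, -0.025 with an offset of 10, -0.017 with no background correction, -0.017 with both channels above background and -0.017 in fry, but passed as higher at 0.33 with median centring. Keratinocyte differentiation stood at -0.019 with processed signals. With median centring the unfolded protein response stood at 0.26, heat shock proteins at 0.20, mesenchymal genes at 0.13, translation initiation factors at 0.26 and DEAD-box helicases at 0.15. Relative to all genes, cholesterol, basal keratinocyte, growth factor and p53 medians stayed below 0, and YAP turned (0.074). With no normalization the unfolded protein response stood at 0.56, heat shock proteins at 0.49, translation initiation factors at 0.55 and helicases at 0.45.

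The values deposited for the series as a measure of expression were not run, since they are p-values, and the slide as a block was not run, since there is 1 slide. The ratio within each array already pairs the RNAs of a replicate, so no separate block for the replicate was fitted. Signal over background limits the dimmest genes: with no filter 43392 genes were tested, with 5403 higher and 5869 lower.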

Other observations

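Gene families were grouped by symbol after the data were seen, with chromosomes and kinds of transcript, and 19 of 231 such sets passed camera (Benjamini-Hochberg over the 231). Among them were RPL and RPS genes, whose calls were lost with processed signals (adjusted p = 0.588 and 0.401). None of the 19 passed with an estimated correlation (adjusted p = 0.984 with an estimated correlation for each named here). With 2 arrays that test has 1 residual degree of freedom per gene, so this says little about them. Metallothioneins, which bind zinc and copper, were higher: 9 of 10 rose, with a median of 0.70 (camera adjusted p = 7.08e-05). MT1X stood at 0.96 ± 0.18 (SD, n = 2), MT2A at 0.92 ± 0.23 and MT1E at 0.74 ± 0.15, while MT1G was not called at -0.03 ± 0.067. The family was also higher with processed signals, median centring and no normalization (adjusted p = 0.0334, 0.000423 and 0.0267). Of the 10, MT2A, MT1A, MT1B, MT1E and MT1HL1 lay above a mean log2 intensity of 16, where loess left a rise (median 0.30 for 195 genes other than ribosomal protein genes), so that rise may account for part of their values. Members of the family are near-identical and their probes may not separate them (the median was 0.50 with processed signals). DENN domain genes, regulators of RAB proteins, rose for 10 of 17 and fell for 1 (median 0.22; camera adjusted p = 0.0101; 0.0513 with no normalization). DENND6A stood at 0.86 ± 0.16 and DENND5A at 0.76 ± 0.096.

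Some complexes were lower as fitted, with camera downward in the other 3 scalings as well but no call in any of them. Of 23 nucleoporin genes 12 fell and 1 rose (median -0.21; camera adjusted p = 0.0162), with NUP50 at -0.50 ± 0.074 (SD, n = 2) and NUP205 at -0.48 ± 0.055, but with median centring the call was lost (adjusted p = 0.823), at a median of -0.054 relative to all genes. Subunits of the proteasome cap (PSMD) fell for 10 of 14 and rose for 2 (median -0.23; camera adjusted p = 0.0156), with PSMD11 at -0.78 ± 0.062 and PSMD13 at -0.70 ± 0.06, but with median centring the call was lost (adjusted p = 0.948) and the median was 0.042 relative to all genes. Among 11 CHMP genes of the ESCRT machinery 8 fell and 1 rose (median -0.33; camera adjusted p = 0.0283), and with median centring the call was lost (adjusted p = 0.460), at a median of -0.17 relative to all genes.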
